A study of Mus musculus with 56 samples.

How the data were processed

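Per the labels, liver RNA of 56 male CD-1 mice in 14 groups was isolated with RNeasy columns, labelled with an Enzo single-round kit and hybridised to Affymetrix mouse arrays of 45101 probe sets, 1 mouse per array. Per the submitters' processing notes the values came from RMA, whose version and settings are not given in the sources used here. The deposited values are intensity values on a linear scale, background-corrected and normalized between arrays by the authors, and were converted to log2. The plan had assumed log2 values, and the scale was settled from the values themselves, whose highest lay between 32516 and 161420. The 37 single-dose arrays shared a lowest value of 4.56 and the 19 arrays of the 2-week study had lowest values of 6.10 to 6.92, so each set was fitted on its own, and whether they were processed apart is not given in the sources used here. The array number limits the precision of each value.

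Genes were assigned to probe sets by the series' own annotation, in which 34958 probe sets had 1 gene, 932 several and 9211 none, and only the first were used. Of the named probe sets 34754 were matched by gene ID. For a gene with several probe sets, the 1 with the highest mean over all arrays was taken. A probe set was kept if it lay at or above the 40th percentile of an array on at least 3 arrays, which removed 3740 genes from the 2-week fit and none from the single-dose fit, where that percentile is the floor itself. This left 18194 and 14454 genes, of which 9134 and 13812 reached an intensity of 32 on at least 3 arrays, and 3231 lay at the floor on all single-dose arrays. An intensity of 32 was also the limit under which a gene is called dim.

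All comparisons used limma 3.58.1 in R 4.3.3, with 1 linear model per set over its 11 or 3 groups, empirical Bayes moderation and Benjamini-Hochberg adjustment within a comparison, at a threshold of 0.05. Each treatment was compared with the vehicle mice of its own time, the sequences were compared with one another at matched times, and a pair of interactions compared the HTS-3 effect at 16 h with that at 8 h and the TS-2 effect at 72 h with that at 8 h, 18 comparisons in all. Comparisons, tests, filter, gene lists and the rule for naming genes were chosen before the data were examined. The gene lists were 28 sets of known targets and cell markers, with 498 of 542 members measured, tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 28 lists of a comparison. Of 504 list tests 111 passed with the preset correlation and 14 with the estimated one. Within a list, genes were also adjusted over the list alone.

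Named genes were those in a fixed panel of 28, of which 26 were measured, the 8 largest rises and falls per comparison among genes past the test whose groups were wholly apart, up to 4 members of each list with the largest change past the test and up to 4 members of a list that passed, and for interactions the 5 smallest adjusted p values in each direction. Of these, 431 results outside the interactions passed the test, 395 of them in the stated direction in every mouse of the first group and 290 with the groups wholly apart. Single genes that are set beside a list without having passed are given with their adjusted p.

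The fit was tested on simulated data, made as normal noise with each gene's residual SD around its vehicle mean, with 100 genes changed 2-fold and 100 changed 4-fold. For TS-2 against vehicle at 8 h it recovered 56% and 91% of them with 9 false calls, for HTS-3 at 16 h 56% and 93% with 5, and for TS-2 at 2 weeks 95% and 100% with 10. Pairing by the replicate number was checked as the correlation of deviations from group means between mice of the same number. In 1 of 16 comparisons, TS-2 against vehicle at 8 h, every pair exceeded 0.1, and over all 16 the correlations ran from -0.50 to 0.47. A fit with the replicate number as a block was among the alternatives.

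The other alternatives were the mean of a gene's probe sets, no filter, quantile normalization, array weights, a fit on the compared groups alone, vehicle mice 1 to 5 or 6 to 10 as the only controls, the HTS-3 sample whose title and description give different times moved from 8 to 16 h, and leaving out each mouse in turn. Chosen after seeing the data were a filter at an intensity of 32 on at least 3 arrays, the Actb 3'/5' log2 ratio of each array as a covariate for RNA quality, and leaving out each mouse for the lists. Gene lengths were taken from the GRCm38.p6 annotation for 99.1% of the single-dose genes, and the median length of the genes called lower was set against 10000 random sets of the same size matched on mean level, with the upper limit of those sets given beside it. Arrays were checked for identical values over 666 and 171 pairs, and none were found. Probe sets without a gene were tested only as a count, and pathology scores and targets of the sequences were not used here.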

Results

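Liver RNA of 56 male CD-1 mice, an outbred strain, was profiled on Affymetrix arrays of 45101 probe sets, 1 array per mouse. The mice had received vehicle (Dulbecco's phosphate buffered saline) or 1 of 3 locked nucleic acid (LNA) gapmers by subcutaneous injection of 25 mg/kg. LNA gapmers are antisense oligonucleotides whose modified ends flank a DNA stretch that lets RNase H cut the bound RNA. The labels name the sequences non-toxic (NTS-1), toxic (TS-2) and severely toxic (HTS-3), and their targets are not given in the sources used here. Groups of 10 mice were dosed for each time point, and 3 or 4 livers per group with the highest-ranking score of minor hepatic hypertrophy were taken for the single-dose arrays, so that these groups do not represent all dosed mice. After a single dose the arrays covered 8, 16 and 72 h for vehicle (3 mice at each time), NTS-1 (3, 4 and 3 mice) and TS-2 (4, 3 and 4 mice), and 8 and 16 h for HTS-3 (3 and 4 mice), because the HTS-3 mice meant for 72 h died or were killed moribund at 48 h or later. After 2 weeks of dosing on days 1, 4, 8 and 11, with livers taken on day 14, there were 10 vehicle, 4 NTS-1 and 5 TS-2 mice.

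The single-dose arrays shared a floor at an intensity of 4.56 that held 44.1% to 47.3% of the probe sets of an array, and 32.1% to 33.3% of probe sets reached an intensity of 32. On the 2-week arrays no common floor was seen and 54.3% to 57.5% of probe sets reached 32, so levels were compared only within each set. The number of arrays limits the precision of every value. Correlations between mice of a group, over genes whose mean log2 level reached that of an intensity of 32, lay between 0.929 and 0.992, with the lowest values in TS-2 at 72 h (0.929), TS-2 at 2 weeks (0.938) and HTS-3 at 16 h (0.944). No pair of arrays held identical values. Changes are log2 ratios with the SE of the limma fit, adjusted p values are Benjamini-Hochberg values of that fit, and a gene passed the test at an adjusted p under 0.05. List members are counted past the test over all genes and, where so stated, with p adjusted over the list alone, and lists named without values passed only at the preset correlation. Genes under 32 on all arrays of a group are called dim there, and folds against a dim group, or a group whose mean lay under 32, are given as lower limits, with values under 32 taken as 32. Of 431 gene results that passed and were eligible for naming, 395 went the stated way in every mouse of the first group, relative to the mean of the other group, and the number of mice is given where one that is named did not.

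NTS-1 was compared with vehicle to show what a gapmer called non-toxic does to liver transcripts. At 8 h (n = 3 against 3) genes switched on by type I interferon rose most. Usp18, a brake on interferon receptor signalling, was 66.7-fold higher (log2 change 6.06 ± 0.64, adjusted p = 5.92e-07, 43.2-fold without vehicle mouse 1). Ifit1, Ifit2 and Ifit3, which bind viral RNA and restrict its translation, were 159.8-fold (32 or more on 2 of 3 vehicle arrays, 97.8-fold without vehicle mouse 1), 51.8-fold and 65.9-fold higher, with log2 changes of 7.32 ± 0.85, 5.70 ± 0.50 and 6.04 ± 0.63. Cxcl10, a chemokine that draws T cells, was 26.7-fold higher (log2 change 4.74 ± 0.79, adjusted p = 7.75e-04). Of the 22 measured members of the interferon list 21 rose, and all 22 rose over the list alone, with a median log2 change of 3.56 (adjusted p = 2.95e-144, or 1.76e-08 with an estimated correlation). The macrophage list had a median of 0.62 (adjusted p = 1.02e-09, or 0.123 with an estimated correlation). Of the 18 members 1 passed the test and 4 over the list alone. The member past the test, the IgG receptor Fcgr1, was at least 6.92-fold higher (adjusted p = 1.88e-04, 32 or more on 1 of 3 vehicle arrays). Mlkl, the executioner of necroptosis, was 3.91-fold higher (log2 change 1.97 ± 0.33, adjusted p = 9.92e-04), and the apoptosis and necroptosis list moved up with a median of 0.16 and a mean of 0.43 with 1 member past the test and 2 over the list alone (adjusted p = 1.23e-04, or 0.0349 with an estimated correlation). The lymphocyte (up) and cholesterol (down) lists also passed, each lost without at least 1 mouse. In all 111 genes passed, 92 higher and 19 lower, and 83 of them by 2-fold or more. Of the 111, 28 were dim in both groups, 18 of these among the 19 that were lower. The count was 10 when limma was fitted on the compared groups alone and 233 with array weights.

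At 16 h (n = 4 against 3) interferon-stimulated genes were again higher. Irf7, the transcription factor that amplifies the interferon response, was 17.8-fold higher (log2 change 4.16 ± 0.38, adjusted p = 5.63e-07). Oas1a, a sensor of double-stranded RNA, was 6.66-fold higher (log2 change 2.74 ± 0.26, adjusted p = 7.37e-07). Of 22 measured interferon genes 13 rose (7 without vehicle mouse 2 or NTS-1 mouse 2 or 4), and 18 over the list alone, with a median log2 change of 2.34 (adjusted p = 2.86e-88, or 2.14e-06 with an estimated correlation). Usp18 was 9.14-fold higher (log2 change 3.19 ± 0.60, adjusted p = 0.0144), a call lost without vehicle mouse 1 (adjusted p = 0.0707), vehicle mouse 2 (adjusted p = 0.086), NTS-1 mouse 2 (adjusted p = 0.0859) or NTS-1 mouse 4 (adjusted p = 0.0525). The list of cytokines, chemokines and NF-kappaB targets moved up with a median of 0.10, no member past the test over all genes or over the list alone (adjusted p = 9.82e-04, or 0.00615 with an estimated correlation), and was lost without vehicle mouse 2 (adjusted p = 0.0575). Cxcl10 stood at a log2 change of 2.26 ± 0.74, adjusted p = 0.826. Neutrophil transcripts had a median of -1.38, with 0 of 12 members past the limma test and 8 over the list alone (adjusted p = 5.46e-14, or 0.0573 with an estimated correlation). That shift rested on 1 of the 3 vehicle mice, vehicle 16 h mouse 1, without which the median was 0 (adjusted p = 0.522), against -2.09 without vehicle mouse 2 or 3. The neutrophil list score, the mean log2 intensity over its members, was 4.41 ± 2.17 (SD, n = 3) in the 16 h vehicle mice. The endoplasmic reticulum folding (up) and stellate cell and matrix and lysosome (down) lists also passed, each lost without at least 1 mouse. In all 27 genes passed, 23 higher and 4 lower, 5 of them dim in both groups. The count was 17 and 16 without NTS-1 mouse 2 or 4, 0 on the compared groups alone and 179 with array weights, of which 70 were higher and 109 lower.

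At 72 h (n = 3 against 3) limma called 0 genes, with 793 genes at an unadjusted p under 0.05, and 0 when only genes at 32 or more on at least 3 arrays were tested. Macrophage transcripts were higher as a list, with a median log2 change of 0.77 over 18 genes, 0 past the test over all genes and 8 over the list alone (adjusted p = 1.42e-19, or 0.03 with an estimated correlation). Cd68, a lysosomal protein of macrophages, had a log2 change of 1.06 ± 0.46, adjusted p = 0.917. Ccl5, a T cell chemokine, and Cxcl9, an interferon-gamma-induced chemokine, had log2 changes of 1.40 ± 0.45 (adjusted p = 0.858, 32 or more on all 3 NTS-1 arrays and no vehicle array) and 1.39 ± 0.58 (adjusted p = 0.882). Their list, cytokines and chemokines, passed with a median of 0.01 and a mean of 0.29 (adjusted p = 0.00713, or 0.03 with an estimated correlation), and was lost without vehicle mouse 1 (adjusted p = 0.0775) or NTS-1 mouse 2 (adjusted p = 0.0551). The interferon list kept a median of 0.36 with 0 members past either adjustment (adjusted p = 4.03e-05, or 0.461 with an estimated correlation), and Usp18 had a log2 change of 1.11 ± 0.64, adjusted p = 1. The cytochrome P450 (down) list also passed, lost without at least 1 mouse. The count of genes was 2, 10 and 4 without vehicle mouse 1, 2 or 3, and 5, 4 and 8 without NTS-1 mouse 1, 2 or 3. It was 9 with array weights and 1 when the mean of a gene's probe sets was used.

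TS-2 was compared with vehicle to follow a gapmer called toxic. At 8 h (n = 4 against 3) 8 genes passed, 1 higher and 7 lower. All 8 were dim in both groups, so no fold is given. With the filter at 32 limma called 0 genes (942 of all genes had an unadjusted p under 0.05). All 8, including Nrg4 (higher) and Cables1 (lower), were called alike after HTS-3 against the same vehicle mice. The macrophage list had a median of 0.19 (adjusted p = 8.61e-04, or 0.964 with an estimated correlation), with 0 of 18 members past either adjustment, and was lost without vehicle mouse 1 (adjusted p = 0.0584) or TS-2 mouse 3 (adjusted p = 0.0697). Replicate numbers may pair these mice by the correlation of their deviations, and 3 genes passed with the number as a block. The count was 20, 34 and 201 without vehicle mouse 1, 2 or 3, 4, 3 and 5 without TS-2 mouse 1, 2 or 4 (3 of these 5 higher), and 112 with array weights.

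At 16 h (n = 3 against 3) Zfp24, a zinc finger transcription factor, was 2.49-fold lower (log2 change -1.32 ± 0.21, adjusted p = 0.0062). It was the only 1 of the 3 genes past the test that was measured above 32, since Ripor2 and Myl9 were lower but dim in both groups. The Zfp24 call was lost without TS-2 mouse 1 (adjusted p = 0.0569) or TS-2 mouse 3 (adjusted p = 0.0694). Neutrophil transcripts had a median log2 change of -1.45 (adjusted p = 9.37e-16, or 0.0668 with an estimated correlation). Of the 12 members 0 passed the test and 10 over the list alone. S100a8, a calcium-binding protein of neutrophils, had a log2 change of -2.99 ± 1.07, adjusted p = 0.915, or -0.97 without vehicle 16 h mouse 1. The acute phase list had a median of -0.23 and a mean of -0.61 (adjusted p = 1.95e-10, or 0.0668 with an estimated correlation). Of the 25 members 0 passed the test and 1 over the list alone. The interferon list had a median of -0.61 (adjusted p = 1.02e-11, or 0.0668 with an estimated correlation), with 0 of 22 members past either adjustment, and the macrophage list a median of -0.38, 0 of 18 past either adjustment (adjusted p = 2.02e-05, or 0.28 with an estimated correlation). Without vehicle 16 h mouse 1 the neutrophil median was 0 (-2.16 without vehicle mouse 2 or 3) and the macrophage median 0.0063, both with adjusted p = 0.886. Genes of endoplasmic reticulum folding had a median of 0.10 (adjusted p = 0.0143, or 0.605 with an estimated correlation). Of the 17 members 0 passed the test and 2 over the list alone, led by Herpud1, which acts in the removal of misfolded proteins (log2 change of 1.28 ± 0.37, adjusted p = 0.811). Their median was -0.15 without vehicle 16 h mouse 1. The RNase H and RNA decay (up) and red blood cell, G2 and mitosis, coagulation and complement and lysosome (down) lists also passed, lost without at least 1 mouse for all but the RNase H and RNA decay list. The count of 3 became 10, 5 and 8 without vehicle mouse 1, 2 or 3, and 334 with array weights. Without TS-2 mouse 1 or 3 it was 1 and 5 (3 higher). It was 1 with the compared groups alone (higher) or the filter at 32 (792 genes had an unadjusted p under 0.05).

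At 72 h (n = 4 against 3) 25 genes passed after TS-2, 2 higher and 23 lower. Myo1e, a membrane-associated myosin, was at least 7.35-fold lower (adjusted p = 1.52e-06, 32 or more on 1 of 4 TS-2 arrays). Cadps2, a protein of vesicle release, was 13.2-fold lower (log2 change -3.72 ± 0.53, adjusted p = 3.73e-04, 32 or more on 3 of 4 TS-2 arrays). Mtss1, a membrane-bending actin regulator, was 6.59-fold lower (log2 change -2.72 ± 0.35, adjusted p = 7.61e-05). Zfp24 was 5.05-fold lower (log2 change -2.34 ± 0.20, adjusted p = 3.33e-08). Met, the hepatocyte growth factor receptor, was 4.91-fold lower (log2 change -2.30 ± 0.33, adjusted p = 4.71e-04). Cxadr, a junction protein that binds coxsackievirus and adenovirus, was 4.58-fold lower (log2 change -2.20 ± 0.36, adjusted p = 0.00322). The Golgi protein Tmf1 was at least 4.83-fold lower (adjusted p = 1.89e-05, 32 or more on 1 of 4 TS-2 arrays). The genes called lower were long, with a median of 69.3 kb against 23.5 kb in random sets of genes matched on mean level, and 11 of the 23 spanned 100 kb or more. No list passed with an estimated correlation. The fatty acid synthesis list had a median of -0.26 (adjusted p = 2.74e-04, or 0.696 with an estimated correlation), with 0 of 18 members past either adjustment, and was lost without vehicle mouse 1 (adjusted p = 0.0591). Markers of sinusoidal endothelium had a median of -0.26 (adjusted p = 4.47e-04, or 0.482 with an estimated correlation). Of the 14 members 0 passed the test and 1 over the list alone, and the list was lost without vehicle mouse 2 (adjusted p = 0.102) or TS-2 mouse 3 (adjusted p = 0.62). The apoptosis and necroptosis (up) and cytochrome P450, urea cycle and gluconeogenesis (down) lists also passed, lost without at least 1 mouse for all but the apoptosis and necroptosis list. Cdkn1a, the cell cycle inhibitor that p53 induces, had a log2 change of -0.84 ± 0.55, adjusted p = 1. Correlations between the TS-2 mice went down to 0.929. The count of 25 was 15 and 52 (23 higher and 29 lower) without TS-2 mouse 1 or 3. It was 22 with the filter at 32 (all lower), 0 on the compared groups alone and 50 with array weights (16 higher, 34 lower).

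HTS-3 was compared with vehicle at the times before the mice died. At 8 h (n = 3 against 3) Afdn, the adherens junction protein afadin, was at least 19.7-fold lower (adjusted p = 9.80e-12), and every HTS-3 mouse lay below every vehicle mouse. The transcription factor Elf1 was 7.36-fold lower (log2 change -2.88 ± 0.31, adjusted p = 4.44e-06, 32 or more on 2 of 3 HTS-3 arrays). Macrophage transcripts had a median log2 change of 1.00 (adjusted p = 4.55e-14, or 0.0695 with an estimated correlation). Of the 18 members 1 passed the test (0 without vehicle mouse 1 or 3 or HTS-3 mouse 1 and 4 without HTS-3 mouse 2 or 3) and 11 over the list alone. Interferon-stimulated genes had a median of 1.00 (adjusted p = 3.16e-11, or 0.106 with an estimated correlation). Of the 22 members 0 passed the test and 10 over the list alone, with Usp18 at a log2 change of 2.22 ± 0.64, adjusted p = 0.134. All 20 measured genes of cholesterol synthesis were lower, with a median of -0.80, 0 past the test and 7 over the list alone (adjusted p = 4.55e-14, or 0.106 with an estimated correlation). Among them were Mvd and Hmgcs1 of the mevalonate pathway, with log2 changes of -1.58 ± 0.52 (adjusted p = 0.225) and -1.30 ± 0.47 (adjusted p = 0.289).

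Some cell cycle genes were also higher 8 h after HTS-3. Pclaf, which binds the replication clamp PCNA, was at least 2.52-fold higher (adjusted p = 0.00171). Cdk1, the kinase of mitotic entry, was 2.64-fold higher (log2 change 1.40 ± 0.29, adjusted p = 0.0178), a call lost without vehicle mouse 1 (adjusted p = 0.0684) or vehicle mouse 3 (adjusted p = 0.0549). The G2 and mitosis list had a median of 0.04 and a mean of 0.40 (adjusted p = 1.77e-07, or 1.09e-04 with an estimated correlation). Its log2 scores, 2.97 for vehicle and 3.37 for HTS-3, were dim. Of the 20 members 2 passed the test (0 without vehicle mouse 1 or 3, 5 without HTS-3 mouse 2 and 6 without HTS-3 mouse 1) and 8 over the list alone. The G1/S list had a median of 0.34, with 1 of 20 past either adjustment (over all genes 0 without vehicle mouse 1 or 3 or HTS-3 mouse 1 or 3 and 2 without HTS-3 mouse 2) (adjusted p = 2.86e-04, or 0.106 with an estimated correlation), and was lost without HTS-3 mouse 1 (adjusted p = 0.0523). The serum amyloid gene Saa2, an acute phase protein, was 4.52-fold higher (log2 change 2.18 ± 0.45, adjusted p = 0.0178), a call lost without vehicle mouse 2 (adjusted p = 0.0532) or vehicle mouse 3 (adjusted p = 0.0549). The apoptosis and necroptosis (up) list also passed, lost without at least 1 mouse. In all 107 genes passed, 30 higher and 77 lower, 53 by 2-fold or more and 35 dim in both groups. The genes called lower had a median length of 64.3 kb against 23.1 kb in level-matched random sets, and 27 of 77 spanned 100 kb or more. The excess of lower genes turned without any 1 HTS-3 mouse. Counts were 277, 370 and 74 higher and 84, 178 and 54 lower without mouse 1, 2 or 3. Correlations between the 3 mice went down to 0.951, and the count was 4 on the compared groups alone and 543 with array weights (277 higher and 266 lower). HTS-3 mouse 3, titled 8 h but described as 16 h, was kept at 8 h. With it moved, 57 genes were higher and 42 lower.

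**Figure D1:**
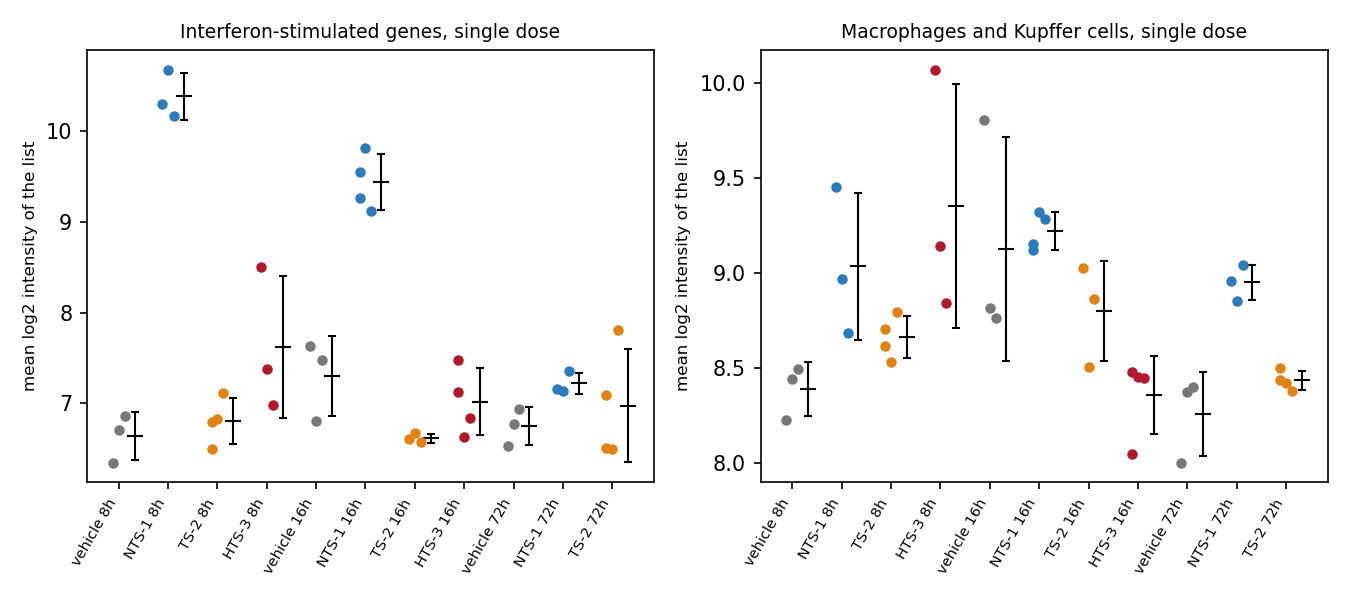
List scores of interferon-stimulated genes (first panel) and of macrophages and Kupffer cells (second panel), as mean log2 intensity over the list, for each mouse of the 11 single-dose groups; points are mice and black dashes with bars the mean ± SD. The 3 NTS-1 mice at 8 h have a mean interferon score of 10.38, against 6.64 in the 8 h vehicle mice.

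At 16 h after HTS-3 (n = 4 against 3) 1337 genes passed, 603 higher and 734 lower, and of the 640 that changed 2-fold or more 477 were lower. Afdn was at least 18.4-fold lower (adjusted p = 7.60e-14). Ptprg, a receptor tyrosine phosphatase, was at least 13.7-fold lower (adjusted p = 2.24e-09). Dock4, an activator of Rac, was at least 5.72-fold lower (adjusted p = 1.14e-12). The adhesion receptor gene Adgrv1 was 33.0-fold lower (log2 change -5.05 ± 0.57, adjusted p = 5.88e-07, 32 or more on 3 of 4 HTS-3 arrays, 21.9-fold without HTS-3 mouse 2). Hamp, the liver hormone that limits iron uptake, fell in all 4 mice and was 3.58-fold lower (log2 change -1.84 ± 0.10, adjusted p = 9.02e-13). Tek, the endothelial receptor of angiopoietins, was 14.5-fold lower (log2 change -3.86 ± 0.43, adjusted p = 3.74e-07, 32 or more on 2 of 4 HTS-3 arrays). Stab2, the hyaluronan scavenger receptor of sinusoidal endothelium, was 2.89-fold lower (log2 change -1.53 ± 0.36, adjusted p = 0.00616), but Stab1 of the same cells was 2.44-fold higher (log2 change 1.29 ± 0.32, adjusted p = 0.00926), a call lost without vehicle mouse 1 (adjusted p = 0.0502) or HTS-3 mouse 4 (adjusted p = 0.0509). The endothelium list did not pass (adjusted p = 0.152). The circadian activator Clock was 3.06-fold lower (log2 change -1.61 ± 0.35, adjusted p = 0.00306). Of 23 p53 targets 3 were higher and 1 lower, over all genes and over the list alone, and the list did not pass (adjusted p = 0.185). The lower member was the death receptor Fas, 2.59-fold lower (log2 change -1.37 ± 0.33, adjusted p = 0.00748). Among the higher was Cdkn1a, 3.53-fold higher (log2 change 1.82 ± 0.55, adjusted p = 0.0422), a call lost without vehicle mouse 1 (adjusted p = 0.18), vehicle mouse 2 (adjusted p = 0.102), HTS-3 mouse 2 (adjusted p = 0.0989), HTS-3 mouse 3 (adjusted p = 0.0595) or HTS-3 mouse 4 (adjusted p = 0.103). The genes called lower had a median length of 92.7 kb against 24.0 kb in level-matched random sets, and 344 of 734 spanned 100 kb or more, while the median of the genes called higher was 16.0 kb.

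Among the genes that rose 16 h after HTS-3, Mycl, a transcription factor of the Myc family, was 4.68-fold higher (log2 change 2.23 ± 0.47, adjusted p = 0.00239, 32 or more on 2 of 3 vehicle arrays). Mthfd2, of mitochondrial folate metabolism, was 1.86-fold higher (log2 change 0.89 ± 0.20, adjusted p = 0.00408). Angptl4, an inhibitor of lipoprotein lipase, was 2.73-fold higher (log2 change 1.45 ± 0.31, adjusted p = 0.00258). The list of the integrated stress response moved up with a median of 0.37, 2 of 23 members past either adjustment (over all genes 1 without vehicle mouse 1 or 2 or HTS-3 mouse 1 or 3) (adjusted p = 0.0107, or 0.442 with an estimated correlation), and the acute phase list down with a median of -0.19 and a mean of -0.54, 2 of 25 past either adjustment (over all genes 1 without vehicle mouse 1 or HTS-3 mouse 2, 4 without vehicle mouse 3 and 5 without vehicle mouse 2) (adjusted p = 7.72e-04, or 0.475 with an estimated correlation). Macrophage transcripts were lower for all 18 members, with a median of -0.84, 5 past the test (0 without vehicle mouse 1 and 2 without HTS-3 mouse 1 or 4) and 8 over the list alone (adjusted p = 1.33e-06, or 0.442 with an estimated correlation). Of these, the complement component C1qa was 1.97-fold lower (log2 change -0.97 ± 0.22, adjusted p = 0.00383), a call lost without vehicle mouse 1 (adjusted p = 0.0669). The neutrophil list had a median of -1.42 (adjusted p = 2.62e-05, or 0.475 with an estimated correlation). Of the 12 members 0 passed the test and 10 over the list alone, and the median was 0 without vehicle 16 h mouse 1 (adjusted p = 0.973) and -2.13 without vehicle mouse 2 or 3. The PPAR-alpha (up) list also passed, lost without at least 1 mouse. The Actb 3'/5' log2 ratio, a measure of RNA quality, was 1.49 ± 0.26 (SD, n = 4) after HTS-3 and 1.40 ± 0.21 (SD, n = 3) after vehicle. Correlations between the HTS-3 mice went down to 0.944, and the count without 1 mouse lay between 928 and 1691. Higher genes outnumbered lower ones without HTS-3 mouse 3 (860 against 831), after quantile normalization (794 against 781) and with the Actb ratio as a covariate (1193 against 926). The count was 59 on the compared groups alone, 2119 with the Actb ratio as a covariate and 827 with the sample described as 16 h moved to this group.

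**Figure D2:**
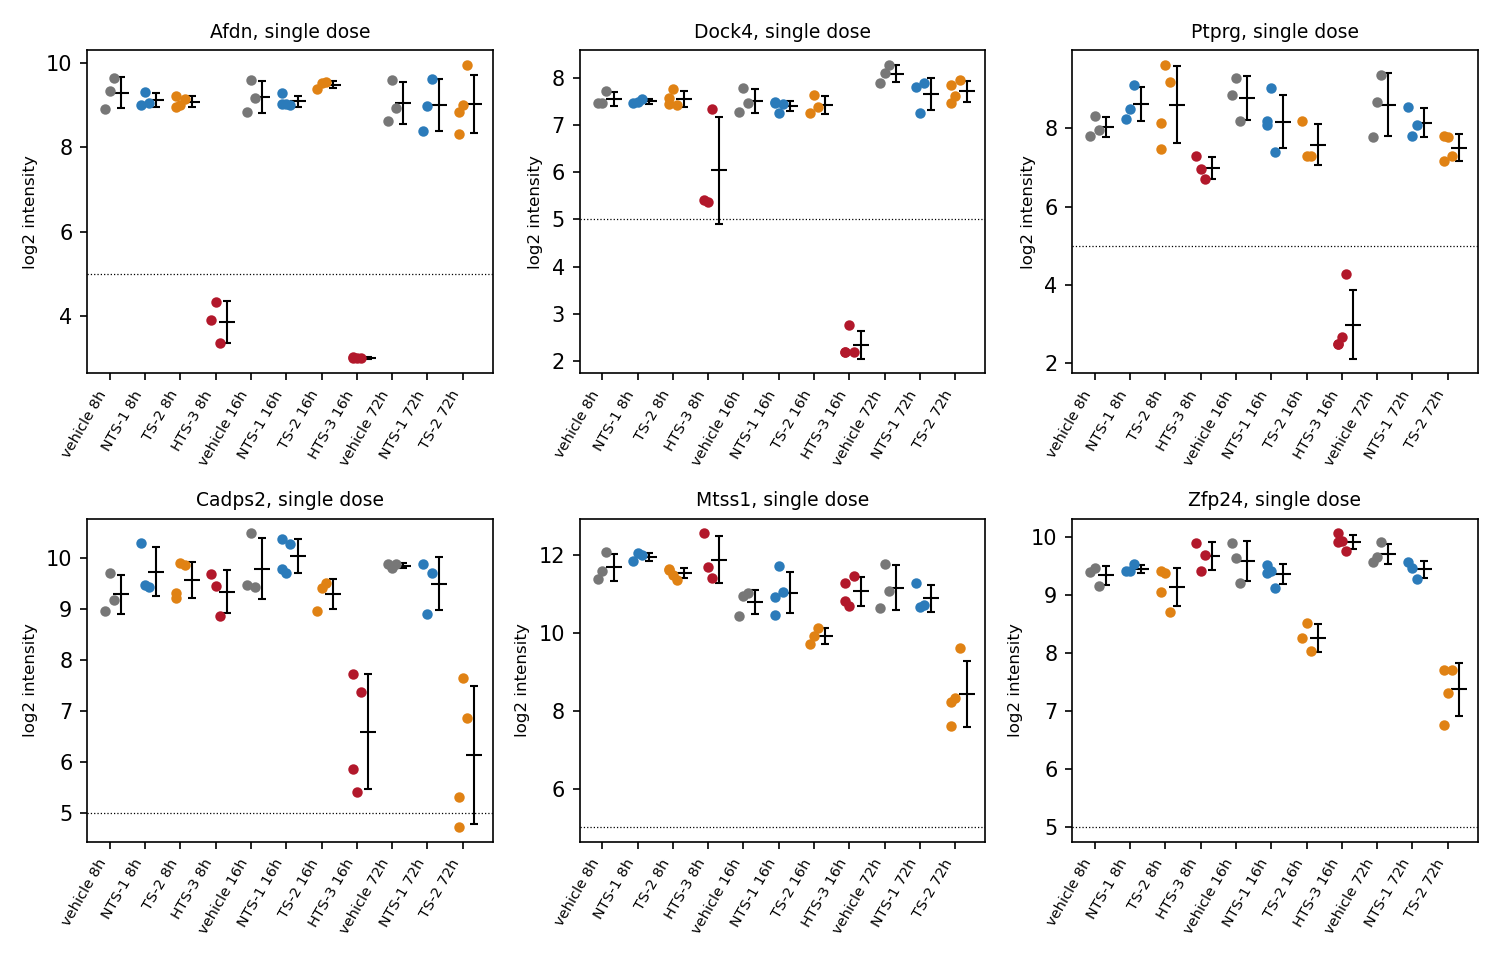
Log2 intensity of Afdn, Dock4, Ptprg, Cadps2, Mtss1 and Zfp24 in each mouse of the 11 single-dose groups; points are mice, black dashes with bars the mean ± SD, and the dotted line marks an intensity of 32. Afdn lies under the line in all HTS-3 mice, and Zfp24 is 5.05-fold lower in TS-2 mice than in vehicle mice at 72 h.

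The change of the HTS-3 effect between 8 and 16 h was tested as an interaction (n = 7 HTS-3 and 6 vehicle mice), and 240 genes passed, 44 with a higher and 196 with a lower effect at 16 h. Hamp had a log2 difference of -1.74 ± 0.14 (adjusted p = 5.50e-08), and Dock4 a log2 difference of -3.67 ± 0.42 (adjusted p = 2.23e-05, -3.02 without HTS-3 8 h mouse 3). The effect on macrophage transcripts was lower at 16 h, with a median difference of -1.84, 8 of 18 past the test (4 without vehicle 16 h mouse 1 and 5 without vehicle 8 h mouse 1 or HTS-3 8 h mouse 1) and 13 over the list alone (adjusted p = 1.69e-20, or 0.0124 with an estimated correlation). Fcgr1 had a log2 difference of -4.22 ± 0.69 (adjusted p = 0.00135, -3.52 without vehicle 16 h mouse 1), and C1qb a log2 difference of -2.24 ± 0.42 (adjusted p = 0.0055). The G2 and mitosis list moved the same way, with a median of -0.04 and a mean of -0.59, 2 of 20 past the test (1 without vehicle 8 h mouse 1 or 3 or vehicle 16 h mouse 1 or HTS-3 8 h mouse 2 or HTS-3 16 h mouse 4 and 4 without vehicle 16 h mouse 3) and 5 over the list alone (adjusted p = 2.64e-05, or 0.00186 with an estimated correlation), and Birc5, an inhibitor of apoptosis made in mitosis, had a log2 difference of -3.14 ± 0.63 (adjusted p = 0.00887, -2.16 without vehicle 16 h mouse 1). Interferon genes had a median of -1.35 (adjusted p = 3.90e-09, or 0.163 with an estimated correlation). Of the 22 members 3 passed the test (7 without HTS-3 8 h mouse 3) and 7 over the list alone. The cholesterol list had a median of 0.80 (adjusted p = 1.03e-06, or 0.358 with an estimated correlation), with 0 of 20 members past either adjustment. The PPAR-alpha (up) and acute phase, cytokine and chemokine, neutrophil, endothelium and apoptosis and necroptosis (down) lists also passed, lost without at least 1 mouse for all but the acute phase list. After quantile normalization 82 genes had a higher and 192 a lower effect. The count was 143 without vehicle 8 h mouse 1, 141 without vehicle 16 h mouse 1, 475 without HTS-3 16 h mouse 3, 8 on the compared groups alone, 670 with array weights, 417 with the Actb ratio as a covariate and 72 with the sample described as 16 h moved to 16 h.

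For TS-2 the difference between 72 and 8 h was tested in the same way (n = 8 TS-2 and 6 vehicle mice), and 8 genes passed, 1 with a higher and 7 with a lower effect at 72 h. The small GTPase gene Cdc42 had a log2 difference of -1.26 ± 0.12 (adjusted p = 2.12e-06), Zfp24 a log2 difference of -2.13 ± 0.28 (adjusted p = 2.79e-04), Prkdc, the catalytic subunit of a DNA repair kinase, a log2 difference of -0.74 ± 0.12 (adjusted p = 0.0048), and Tmf1 a log2 difference of -2.95 ± 0.49 (adjusted p = 0.00815). Markers of sinusoidal endothelium had a median difference of -0.45 (adjusted p = 5.57e-04, or 0.943 with an estimated correlation), with 0 of 14 members past either adjustment, and were lost without vehicle 72 h mouse 2 (adjusted p = 0.121) or TS-2 72 h mouse 3 (adjusted p = 0.157). The count was 12, 23 and 26 without vehicle 8 h mouse 1, 2 or 3, of which 7, 17 and 18 had a higher effect at 72 h, so the direction turned. It was 5 without TS-2 8 h mouse 1 or 2, 1 on the compared groups alone and 22 with array weights.

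TS-2 and NTS-1 were compared directly at the same dose and times, to separate effects of a gapmer called toxic from those of 1 called non-toxic. At 8 h (n = 4 against 3) all 92 genes past the test were lower after TS-2. Ifit1 was 205-fold lower (log2 change -7.68 ± 0.80, adjusted p = 4.98e-07, 32 or more on 3 of 4 TS-2 arrays). Usp18 was 35.8-fold lower (log2 change -5.16 ± 0.60, adjusted p = 2.62e-06). Of 22 interferon genes 20 were lower, and 22 over the list alone, with a median of -3.38 (adjusted p = 5.22e-166, or 3.97e-09 with an estimated correlation). Mlkl was 3.39-fold lower (log2 change -1.76 ± 0.31, adjusted p = 0.00204), and the apoptosis and necroptosis list had a median of -0.20 (adjusted p = 2.73e-04, or 0.0412 with an estimated correlation). Of the 14 members 1 passed the test and 2 over the list alone. The endoplasmic reticulum folding and RNase H and RNA decay (up) and acute phase, cytokine and chemokine, macrophage and lymphocyte (down) lists also passed, each lost without at least 1 mouse. For other genes the interval of the difference was narrow, with 95% limits of -0.21 to 0.19 for Hamp, -0.15 to 0.14 for the cytochrome P450 gene Cyp2c29 and -0.20 to 0.07 for albumin (Alb). It was wide for others, at -2.83 to 0.74 for Lcn2 and -1.01 to 0.70 for Saa2. The count was 209 and 231 without NTS-1 mouse 1 or 3, 44 on the compared groups alone and 173 with array weights.

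At 16 h (n = 3 against 4) 42 genes passed, 41 of them lower after TS-2. Irf7 was 21.3-fold lower (log2 change -4.41 ± 0.38, adjusted p = 7.50e-08). Usp18 was 25.4-fold lower (log2 change -4.67 ± 0.60, adjusted p = 3.65e-05). Zbp1, a sensor of left-handed nucleic acid, was 12.9-fold lower (log2 change -3.69 ± 0.61, adjusted p = 0.00169). The interferon list had 16 of 22 members lower, and 20 over the list alone, with a median of -3.19 (adjusted p = 4.73e-120, or 1.14e-07 with an estimated correlation). Its mean score was 7.30 in vehicle, 9.44 in NTS-1 and 6.62 in TS-2 mice. Cytokines and chemokines had a median of -0.10 and a mean of -0.39 (adjusted p = 1.63e-07, or 5.11e-05 with an estimated correlation). Of the 22 members 0 passed the test and 3 over the list alone. The fatty acid synthesis (up) and acute phase, macrophage and G1/S (down) lists also passed, lost without at least 1 mouse for all but the acute phase and macrophage lists. Hamp did not pass, with 95% limits of -0.28 to 0.13, nor did Alb, with limits of -0.25 to 0.02, nor Cdkn1a, with limits of -0.68 to 1.60. The count was 27 without TS-2 mouse 2 and 131 with array weights.

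At 72 h (n = 4 against 3) 31 genes passed, 3 higher and 28 lower after TS-2. Zfp24 was 4.19-fold lower (log2 change -2.07 ± 0.20, adjusted p = 4.81e-07). Mtss1 was 5.47-fold lower (log2 change -2.45 ± 0.35, adjusted p = 6.92e-04). Myo1e was at least 7.36-fold lower (adjusted p = 1.50e-06, 32 or more on 1 of 4 TS-2 arrays). The genes called lower had a median length of 61.5 kb, above the upper limit of 39.3 kb for level-matched random sets. Macrophage transcripts were lower after TS-2 for all 18 members, with a median of -0.56, 0 past the test and 5 over the list alone (adjusted p = 1.10e-10, or 0.146 with an estimated correlation). The endothelium, G2 and mitosis and fatty acid synthesis (down) lists also passed, each lost without at least 1 mouse. The difference in Cd68 had 95% limits of -1.80 to -0.05, that in Cdkn1a -1.77 to 0.51 and that in Saa1 -0.94 to 0.41, and none of them passed. The count was 49 without NTS-1 mouse 1, 48 without TS-2 mouse 3 (21 higher and 27 lower), 1 on the compared groups alone (higher) and 205 with array weights.

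HTS-3 and TS-2 were also set against each other at the times they share. At 8 h (n = 3 against 4) 48 genes passed, 8 higher and 40 lower after HTS-3. Afdn was at least 17.0-fold lower (adjusted p = 5.12e-12). Emcn, a sialomucin of endothelium, was at least 3.57-fold lower (adjusted p = 0.00411). Pclaf was at least 2.51-fold higher (adjusted p = 0.00275, 32 or more on 1 of 4 TS-2 arrays), and the G2 and mitosis list had a median of 0.01 and a mean of 0.35 (adjusted p = 3.61e-09, or 1.95e-05 with an estimated correlation). Of the 20 members 0 passed the test and 8 over the list alone. All 20 cholesterol genes were lower than after TS-2, with a median of -0.72 and 0 past either adjustment (adjusted p = 4.07e-13, or 0.0907 with an estimated correlation). Interferon genes had a median of 0.98 (adjusted p = 1.32e-12, or 0.0792 with an estimated correlation), and of 0.31 without HTS-3 mouse 1. Of the 22 members 0 passed the test and 2 over the list alone. The p53, acute phase, cytokine and chemokine, macrophage, G1/S and apoptosis and necroptosis (up) and endoplasmic reticulum folding (down) lists also passed, lost without at least 1 mouse for all but the macrophage list. Alb, Hamp and Cyp2c29 did not pass, with 95% limits of -0.15 to 0.12, -0.26 to 0.14 and -0.14 to 0.15. The excess of lower genes turned without HTS-3 mouse 1 (332 higher and 64 lower, 396 in all) or 2 (324 and 85, 409 in all), with array weights (411 and 263, 674 in all) and with the sample described as 16 h moved to that time (24 and 17), and was 26 and 27 without HTS-3 mouse 3. The count was 30 without TS-2 mouse 2 and 15 on the compared groups alone.

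At 16 h (n = 4 against 3) 1082 genes passed, 391 higher and 691 lower after HTS-3, and 652 higher and 715 lower after quantile normalization. Afdn was at least 22.5-fold lower (adjusted p = 2.42e-14). Dock4 was at least 5.39-fold lower (adjusted p = 1.71e-12). Nbr1, a receptor of selective autophagy, was 37.3-fold lower (log2 change -5.22 ± 0.56, adjusted p = 1.86e-07, 32 or more on 3 of 4 HTS-3 arrays, 64.5-fold without HTS-3 mouse 3, 24.5-fold without HTS-3 mouse 4). Hamp was 3.66-fold lower (log2 change -1.87 ± 0.10, adjusted p = 5.85e-13). Tek was 15.6-fold lower (log2 change -3.96 ± 0.43, adjusted p = 2.26e-07, 32 or more on 2 of 4 HTS-3 arrays). Stab2 was 3.35-fold lower (log2 change -1.75 ± 0.36, adjusted p = 0.00183). Mycl was 4.90-fold higher (log2 change 2.29 ± 0.47, adjusted p = 0.00193). Endoplasmic reticulum folding genes had a median of -0.40 (adjusted p = 0.0104, or 0.89 with an estimated correlation). Of the 17 members 1 passed the test (0 without TS-2 mouse 1, 2 or 3 or HTS-3 mouse 1, 2 or 4 and 4 without HTS-3 mouse 3) and 3 over the list alone, and the list was lost without HTS-3 mouse 1 (adjusted p = 0.05) or HTS-3 mouse 2 (adjusted p = 0.0663). The integrated stress response and G1/S (up) and macrophage (down) lists also passed, each lost without at least 1 mouse. Cdkn1a did not pass (95% limits of -0.31 to 1.97), nor did Cd68 (limits of -1.50 to 0.25) or Alb (limits of -0.10 to 0.17). The genes called lower had a median length of 93.6 kb, above the limit of 26.6 kb for level-matched random sets. The count was 88 on the compared groups alone, 1697 with array weights and 1657 with the Actb ratio as a covariate, of which 850 were higher and 807 lower.

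Comparisons with the same vehicle mice share their chance values. At 8 h the changes after HTS-3 and TS-2 correlated across genes, which are not independent replicates, with Pearson's r = 0.572 and Spearman's rho = 0.535. Simulated unchanged groups sharing 3 simulated controls gave a mean r of 0.517 and up to 0.801. The covariance was 0.0378 against a simulated 0.0278 with an SD of 0.0159 over 100 simulations. At 16 h r was 0.335 against a simulated mean of 0.526 and up to 0.865, with a covariance of 0.0420 against a simulated 0.0279 and an SD of 0.0158. With 3 vehicle mice no split leaves both parts a pair of them, and the part of any excess that comes from the shared mice was not separated. Adam23, Cadps2, Exoc4, Lpp, Met and Prkcb were called lower both 72 h after TS-2 and 16 h after HTS-3, 6 genes, listed after their values were seen, against 0.928 for independent lists, while 1 gene was called in opposite directions and r across genes was 0.0902. Of 21 TS-2 falls at 72 h tested at 2 weeks, 19 recurred in other mice, against 3.06 for independent lists. Among them were Cadps2, Mtss1, Cxadr and Zfp24.

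After 2 weeks of NTS-1 (n = 4 against 10) 709 genes passed, 270 higher and 439 lower, but only 23 by 2-fold or more, 22 of them lower. Mrc1, the mannose receptor of sinusoidal endothelium and macrophages, was 2.78-fold lower (log2 change -1.47 ± 0.25, adjusted p = 0.00618). Cd55, which protects cells from complement, was at least 2.07-fold lower (adjusted p = 0.00692, 32 or more on 2 of 4 NTS-1 arrays). The transcription factor Nfix was 2.27-fold higher (log2 change 1.18 ± 0.14, adjusted p = 6.07e-04). Sinusoidal endothelium markers had a median of -0.54 (adjusted p = 1.16e-04, or 0.989 with an estimated correlation). Of the 14 members 5 passed the test and 7 over the list alone, all lower. The number of 5 became 0 without NTS-1 mouse 3 or 4, 1 without NTS-1 mouse 2 and 3 without vehicle mouse 3, 4, 5, 6, 8, 9 or 10 or NTS-1 mouse 1. Among them the scavenger-like gene Oit3 was 1.87-fold lower (log2 change -0.90 ± 0.22, adjusted p = 0.0248), a call lost without NTS-1 mouse 2 (adjusted p = 0.0665), NTS-1 mouse 3 (adjusted p = 0.0732) or NTS-1 mouse 4 (adjusted p = 0.0798). Interferon genes had a median of 0.20 (adjusted p = 0.00862, or 0.989 with an estimated correlation). Of the 21 members 0 passed the test and 5 over the list alone, a shift lost without NTS-1 mouse 2 (adjusted p = 0.294). The list of endoplasmic reticulum folding had a median of 0.26 (adjusted p = 0.00872, or 0.989 with an estimated correlation). Of the 17 members 1 passed the test (2 without vehicle mouse 7) and 3 over the list alone, and the list was lost without NTS-1 mouse 4 (adjusted p = 0.125). The coagulation and complement (up) list also passed, lost without at least 1 mouse. Dnajc3, a chaperone cofactor of the folding list, was 1.39-fold higher (log2 change 0.47 ± 0.10, adjusted p = 0.0148).

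The NTS-1 count at 2 weeks moved with single mice. It was 369, 210, 165 and 275 without NTS-1 mouse 1, 2, 3 or 4, and 1325, 449, 433, 454, 434 and 425 without vehicle mouse 2, 3, 4, 5, 6 or 8. With vehicle mice 1 to 5 alone as controls 1 gene passed, and with mice 6 to 10 alone 709, of which 175 were higher and 534 lower. With array weights the count was 1960 and with the Actb ratio as a covariate 1159. After quantile normalization 438 genes were higher and 427 lower.

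After 2 weeks of TS-2 (n = 5 against 10) 5405 genes passed, 3301 higher and 2104 lower, 838 of them by 2-fold or more, and 2735 higher and 2467 lower after quantile normalization. Cdkn1a was 12.3-fold higher (log2 change 3.62 ± 0.56, adjusted p = 5.93e-05, 19.9-fold without TS-2 mouse 1), with TS-2 mouse 1 at a log2 intensity of 8.34 and the highest vehicle mouse at 8.40. Btg2, an antiproliferative p53 target, was 8.96-fold higher (log2 change 3.16 ± 0.55, adjusted p = 1.48e-04). Phlda3, a p53-induced inhibitor of Akt, was 3.95-fold higher (log2 change 1.98 ± 0.42, adjusted p = 8.77e-04). Of 22 p53 targets 14 were higher and 1 lower, over all genes and over the list alone, with a median of 0.64 (adjusted p = 9.40e-04, or 0.791 with an estimated correlation). NRF2 targets, the antioxidant defence genes, had a median of 0.75, 13 of 18 higher and 2 lower, and 14 and 2 over the list alone (adjusted p = 2.26e-04, or 0.791 with an estimated correlation), with Srxn1, which repairs oxidised peroxiredoxins, 4.24-fold higher (log2 change 2.08 ± 0.29, adjusted p = 2.29e-05) and Nqo1, a quinone reductase, 2.58-fold higher (log2 change 1.37 ± 0.28, adjusted p = 7.04e-04). The integrated stress response list had a median of 0.53, 9 of 20 higher and 1 lower, and 10 and 2 over the list alone (adjusted p = 0.024, or 0.791 with an estimated correlation), with the transcription factor gene Atf3 3.38-fold higher (log2 change 1.76 ± 0.38, adjusted p = 0.00127). Apoptosis and necroptosis genes had a median of 0.59, 9 of 14 higher, and 9 higher and 1 lower over the list alone (adjusted p = 0.024, or 0.791 with an estimated correlation), and Tnfrsf12a, the receptor of TWEAK, was 2.52-fold higher (log2 change 1.33 ± 0.33, adjusted p = 0.00323). Cyclin D1 (Ccnd1), which drives entry into the cell cycle, was 4.01-fold higher (log2 change 2.00 ± 0.27, adjusted p = 1.70e-05). The helicase gene Mcm5 was 2.37-fold higher (log2 change 1.24 ± 0.25, adjusted p = 5.93e-04), although neither cell cycle list passed.

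Acute phase and interferon genes were higher in the same mice, but the neutrophil list and that of cytokines, chemokines and NF-kappaB targets did not pass (adjusted p = 0.495 and 0.607). Lcn2, an iron-withholding acute phase protein, was 15.6-fold higher (log2 change 3.96 ± 0.82, adjusted p = 7.97e-04, 32 or more on 9 of 10 vehicle arrays, 26.7-fold without TS-2 mouse 1, 7.73-fold without TS-2 mouse 5). Socs3, a feedback inhibitor of cytokine receptors, was 4.50-fold higher (log2 change 2.17 ± 0.53, adjusted p = 0.00317, 2.92-fold without TS-2 mouse 5), and 14 of 25 acute phase genes were higher, 16 over the list alone, with a median of 0.51 (adjusted p = 0.00188, or 0.791 with an estimated correlation). Usp18 was 9.31-fold higher (log2 change 3.22 ± 0.39, adjusted p = 5.10e-06). Ifit1 was 4.55-fold higher (log2 change 2.18 ± 0.36, adjusted p = 8.84e-05), and 16 of 21 interferon genes rose, 17 over the list alone, with a median of 0.73 (adjusted p = 2.09e-04, or 0.791 with an estimated correlation). Col1a2, a chain of type I collagen, was 2.43-fold higher (log2 change 1.28 ± 0.27, adjusted p = 9.24e-04), and 9 of 18 stellate cell and matrix genes were higher over all genes and over the list alone, with a median of 0.57 (adjusted p = 0.0301, or 0.791 with an estimated correlation), a list lost without TS-2 mouse 3 (adjusted p = 0.101) or TS-2 mouse 5 (adjusted p = 0.149). The macrophage gene Mpeg1, which encodes a pore-forming protein, was 2.73-fold higher (log2 change 1.45 ± 0.33, adjusted p = 0.00158), but the macrophage list did not pass, and TS-2 mouse 5 had a macrophage score of 9.55 against 7.20 to 7.87 in the other 4 TS-2 mice. Sinusoidal endothelium markers were lower for 9 of 14, over all genes and over the list alone, with a median of -0.78 (adjusted p = 2.26e-04, or 0.791 with an estimated correlation), and Dnase1l3, a DNase of these cells and macrophages, was 2.47-fold lower (log2 change -1.31 ± 0.22, adjusted p = 1.32e-04).

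Several genes of liver metabolism were lower after 2 weeks of TS-2. Cyp2b10, a target of the xenobiotic receptor CAR, was 7.46-fold lower (log2 change -2.90 ± 0.34, adjusted p = 4.47e-06, 32 or more on 3 of 5 TS-2 arrays), and of 28 cytochrome P450 and xenobiotic genes 5 were higher and 13 lower, 5 and 14 over the list alone, with a median of -0.22 (adjusted p = 0.024, or 0.791 with an estimated correlation). Cyp8b1, the sterol hydroxylase that makes cholic acid, was 6.31-fold lower (log2 change -2.66 ± 0.67, adjusted p = 0.00393, 9.67-fold without TS-2 mouse 1, 3.16-fold without TS-2 mouse 5). Slc10a1, the bile salt importer of hepatocytes, was 2.64-fold lower (log2 change -1.40 ± 0.28, adjusted p = 5.19e-04). Hal, which breaks down histidine, was 2.34-fold lower (log2 change -1.23 ± 0.18, adjusted p = 3.63e-05), but their lists did not pass. Fatty acid synthesis genes had a median of -0.37, 4 of 18 lower over all genes (2 without TS-2 mouse 4 or 5, 7 without TS-2 mouse 3 and 11 without TS-2 mouse 1) and over the list alone (adjusted p = 0.0479, or 0.791 with an estimated correlation), a list lost without vehicle mouse 1 (adjusted p = 0.0739), vehicle mouse 2 (adjusted p = 0.0562), vehicle mouse 4 (adjusted p = 0.0581), vehicle mouse 7 (adjusted p = 0.0829), vehicle mouse 10 (adjusted p = 0.0649), TS-2 mouse 4 (adjusted p = 0.108) or TS-2 mouse 5 (adjusted p = 0.495). Alas1, the first enzyme of haem synthesis, was 5.65-fold higher (adjusted p = 4.14e-05). The largest falls included Mtss1, 24.0-fold lower (log2 change -4.59 ± 0.27, adjusted p = 9.04e-10, 32 or more on 3 of 5 TS-2 arrays), Cadps2, at least 14.1-fold lower (adjusted p = 1.46e-15), Zfp24, 10.2-fold lower (log2 change -3.35 ± 0.18, adjusted p = 2.64e-10, 32 or more on 4 of 5 TS-2 arrays), and Memo1, a regulator of cell motility, 14.5-fold lower (log2 change -3.85 ± 0.28, adjusted p = 2.06e-08, 32 or more on 4 of 5 TS-2 arrays). The genes called lower had a median length of 21.6 kb, within the limit of 22.0 kb for level-matched random sets, and 364 of 2104 spanned 100 kb or more. The count without 1 mouse lay between 4440 and 5680.

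**Figure D3:**
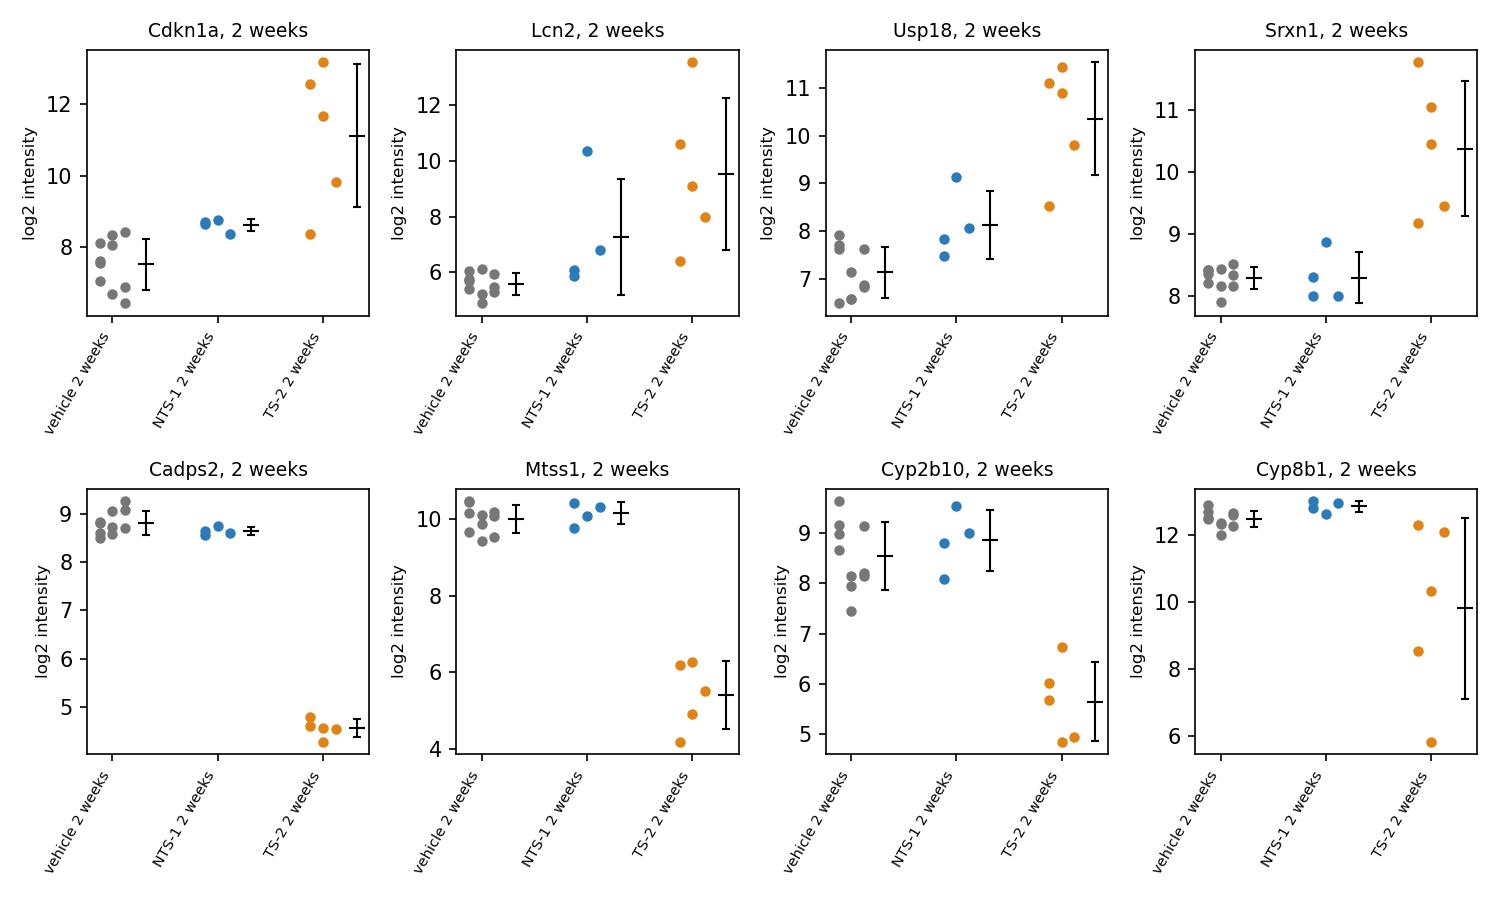
Log2 intensity of Cdkn1a, Lcn2, Usp18, Srxn1, Cadps2, Mtss1, Cyp2b10 and Cyp8b1 in each of the 10 vehicle, 4 NTS-1 and 5 TS-2 mice at 2 weeks; points are mice and black dashes with bars the mean ± SD. Mtss1 is 24.0-fold (32 or more on 3 of 5 TS-2 arrays) and Cadps2 at least 14.1-fold lower in TS-2 than in vehicle mice.

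Set against NTS-1 at 2 weeks (n = 5 against 4), TS-2 gave 3038 genes past the test, 2036 higher and 1002 lower, and 1373 higher and 1359 lower after quantile normalization. Cdkn1a was 5.74-fold higher (log2 change 2.52 ± 0.69, adjusted p = 0.0152, in 4 of 5 mice, 9.28-fold without TS-2 mouse 1). Socs3 was 6.49-fold higher (log2 change 2.70 ± 0.65, adjusted p = 0.00764, 4.21-fold without TS-2 mouse 5). Usp18 was 4.67-fold higher (log2 change 2.22 ± 0.48, adjusted p = 0.00361). Srxn1 was 4.22-fold higher (log2 change 2.08 ± 0.36, adjusted p = 0.00101). Of 22 p53 targets 13 were higher, 15 over the list alone, with a median of 0.75 (adjusted p = 3.56e-05, or 0.678 with an estimated correlation), and of 18 NRF2 targets 11 were higher, 13 over the list alone, with a median of 0.67 (adjusted p = 3.56e-05, or 0.678 with an estimated correlation). Mtss1 was 26.7-fold lower (log2 change -4.74 ± 0.33, adjusted p = 2.72e-08, 32 or more on 3 of 5 TS-2 arrays). Cadps2 was at least 12.5-fold lower (adjusted p = 1.68e-13). Cyp2b10 was 9.22-fold lower (log2 change -3.21 ± 0.42, adjusted p = 1.06e-04, 32 or more on 3 of 5 TS-2 arrays). Cyp8b1 was 8.18-fold lower (log2 change -3.03 ± 0.82, adjusted p = 0.0144, 12.5-fold without TS-2 mouse 1, 4.10-fold without TS-2 mouse 5). Cytochrome P450 genes had a median of -0.31, 4 of 28 higher and 13 lower (5 without NTS-1 mouse 1 or 4, 7 without NTS-1 mouse 3 or TS-2 mouse 2, 4 or 5 and 8 without NTS-1 mouse 2), 5 and 13 over the list alone (adjusted p = 0.00635, or 0.678 with an estimated correlation). The integrated stress response, acute phase, interferon, macrophage, stellate cell and matrix and apoptosis and necroptosis (up) and cholesterol and fatty acid synthesis (down) lists also passed, lost without at least 1 mouse for all but the integrated stress response, stellate cell and matrix and apoptosis and necroptosis lists. The 2 sequences did not differ past the test in Alb, with 95% limits of -0.16 to 0.09, or in Saa1, with limits of -0.60 to 1.60. The count was 1918 and 1969 without NTS-1 mouse 1 or 4, and 1514 on the compared groups alone.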

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

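The tests of a trend with length over all genes and of single NTS-1 mice at 2 weeks were chosen, or worded in their present form, only after their results were seen, and the Actb covariate was chosen after seeing the data.

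Genes called lower were long in 3 comparisons with vehicle, with medians of 69.3 kb for TS-2 at 72 h, 64.3 kb for HTS-3 at 8 h and 92.7 kb for HTS-3 at 16 h. The mean level of these genes is argued against as the whole cause, since the upper limits of level-matched random sets were 43.0, 32.8 and 26.5 kb. RNA quality as measured by the Actb ratio is argued against too, since the median at 16 h after HTS-3 was 76.5 kb with the ratio as a covariate, above a limit of 25.7 kb. A loss of long transcripts that follows the toxicity of the sequence stays open. The lowest Spearman rho of length with change over all genes, many at the floor, was -0.16, and NTS-1 at 72 h had -0.122. The -0.185 to 0.212 of single vehicle mice cannot decide, as they vary more than group means. Genes called lower after 2 weeks of TS-2 were not longer than random sets (median 21.6 kb, limit 22.0 kb). Those called lower than after NTS-1 were (25.0 kb, limit 22.6 kb). Cutting of unintended transcripts by the gapmers, which long genes could offer more often, may also give this pattern. This was not tested, since the sequences are not given in the sources.

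At 2 weeks 709 genes passed after NTS-1, 23 of them by 2-fold or more. A difference between vehicle mice 1 to 5 and 6 to 10 stays open, and whether they belong to different cohorts is not given in the sources used here. Between these sets limma called 0 genes (946 at an unadjusted p under 0.05), fewer than the 35 set in advance for a difference. That limit does not decide, since with the same number of controls 1 gene passed against mice 1 to 5 and 709 against mice 6 to 10, so that the count depends on the set. Cdkn1a, picked after its values were seen, lay at 7.59 or higher in mice 1 to 5 and at 7.55 or lower in mice 6 to 10. That 1 of the NTS-1 mice gave the count stays open, because leaving out any of the 4 lowered it, to 165 at the lowest, as fewer mice also would. An effect of NTS-1 itself, the biological explanation, also stays open.

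HTS-3 mouse 3 at 8 h is described as taken at 16 h. A sample taken at 16 h is argued against by the circadian clock genes, over 12 of which its root mean square log2 distance was 0.859 to the 8 h vehicle mice and 3.30 to the 16 h vehicle mice. All 21 treated arrays of these times were nearer to the vehicle mice of their own time. What the description refers to stays open.

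The HTS-3 effect differed between 16 and 8 h in 240 genes, and the TS-2 effect between 72 and 8 h in 8. In the HTS-3 interaction the macrophage list had a median of -1.84 and the G2 and mitosis list a median of -0.045 with a mean of -0.59. In 7 groups and 8 lists, 56 tests for a mouse far from the others found 4, and chance alone finds about 1 in 20. HTS-3 mouse 1 at 16 h had a macrophage score of 8.05 against 8.45 to 8.48 in the other mice of its group. TS-2 mouse 5 at 2 weeks had a macrophage score of 9.55 against 7.20 to 7.87, and a neutrophil score of 5.98 against 5.51 to 5.61. NTS-1 mouse 2 at 2 weeks had a neutrophil score of 5.96 against 5.65 to 5.70. Among probe sets without a named gene 81 of 866 passed at 16 h after HTS-3, 38 higher and 43 lower, and 429 of 3267 after 2 weeks of TS-2, 206 higher and 223 lower.

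The same mice were also split into other groups of the same sizes, and the number of splits that called as many genes as the real groups was counted, the real split included. Chance was excluded for NTS-1 at 16 h (1 of 35 splits, 27 genes, highest other 9), TS-2 against NTS-1 at 8 h (1 of 35, 92 genes, highest other 25) and at 16 h (1 of 35, 42 genes, highest other 19), and HTS-3 against TS-2 at 8 h (1 of 35, 48 genes, highest other 11). For TS-2 at 8 h (8 genes) 1 of 35 splits called as many and the highest other 6. If the replicate numbers pair these mice, which is unknown, the 8 splits that part 3 pairs are too few for a share under 0.05. The highest other of them called 2, and 3 genes passed with the number as a block. At 2 weeks chance was excluded for TS-2 (1 of 100 drawn splits, 5405 genes, highest other 590), for TS-2 against NTS-1 (2 of 100, 3038 genes, highest other 3680) and for NTS-1 (2 of 100, 709 genes, highest other 969). The splits for NTS-1 take no account of the sets of vehicle mice, and against mice 1 to 5 alone 1 gene passed, so a difference between these sets is not excluded by them. With 3 mice against 3 the 10 splits are too few for a share under 0.05, and the real and highest other counts were 111 and 22 for NTS-1 at 8 h (1 split as large), 0 and 3 for NTS-1 at 72 h (10 as large), 3 and 2 for TS-2 at 16 h (1 as large) and 107 and 21 for HTS-3 at 8 h (1 as large).

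The splits did not exclude chance for TS-2 at 72 h (2 of 35 splits, 25 genes, highest other 55), HTS-3 at 16 h (2 of 35, 1337 genes, highest other 1389) or HTS-3 against TS-2 at 16 h (2 of 35, 1082 genes, highest other 1345). Each higher split moved only treated mouse 3, so a treatment effect stays in its count, and these splits do not decide. Of 21 TS-2 falls at 72 h tested at 2 weeks, 19 were called lower there in other mice, against 3.06 for independent lists. Nor did the splits exclude chance for TS-2 against NTS-1 at 72 h (4 of 35, 31 genes, highest other 115), the HTS-3 interaction (13 of 100, 240 genes, highest other 732) and the TS-2 interaction (6 of 100, 8 genes, highest other 12). The interaction splits exchange treated and vehicle mice within a time, so a treatment effect stays in their counts. In the split that called 732 genes the 16 h mice kept their groups, while HTS-3 8 h mice 1 and 3 stood as vehicle. For the interactions the splits therefore do not decide. The split that called 115 genes, several times the real count, points to a structure of the samples other than their groups, and what it is was not tested.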

How the results depend on the processing

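The filter at an intensity of 32, the Actb covariate and the lists without single mice were chosen after seeing the data. Counts that stayed within 1.5 times are not repeated, and the cause of a change was not tested unless one is given.

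With the mean of a gene's probe sets the count was 1 for NTS-1 at 72 h and 25 for TS-2 at 8 h, and with quantile normalization it was 5 for TS-2 at 8 h. With array weights it was 233, 179 and 9 for NTS-1 at 8, 16 and 72 h, 112, 334 and 50 for TS-2, 543 for HTS-3 at 8 h, 173, 131 and 205 for TS-2 against NTS-1 at 8, 16 and 72 h, 674 and 1697 for HTS-3 against TS-2 at 8 and 16 h, 670 and 22 for the HTS-3 and TS-2 interactions and 1960 for NTS-1 at 2 weeks. With the spread estimated from the compared groups alone, which leaves fewer mice, it was 10 and 0 for NTS-1 at 8 and 16 h (limma, against 1165 and 717 genes at an unadjusted p under 0.05 in the fit of all groups), 0, 1 and 0 for TS-2 at 8, 16 and 72 h (against 942, 792 and 769), 4 and 59 for HTS-3 at 8 and 16 h, 44 and 1 for TS-2 against NTS-1 at 8 and 72 h, 15 and 88 for HTS-3 against TS-2 at 8 and 16 h, 8 and 1 for the HTS-3 and TS-2 interactions and 1514 for TS-2 against NTS-1 at 2 weeks.

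The replicate block gave 3 genes for TS-2 at 8 h, 0 for NTS-1 at 2 weeks (limma, against 2934 genes at an unadjusted p under 0.05 in the fit without it) and 1066 for TS-2 against NTS-1 at 2 weeks. Only for the first of these did the pair correlations all exceed 0.1.

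With the filter at 32, which removes the dim genes, the count was 0 for TS-2 at 8 h and 1 for TS-2 at 16 h. With the Actb covariate it was 2119 for HTS-3 at 16 h, 1657 for HTS-3 against TS-2 at 16 h, 417 for the HTS-3 interaction and 1159 for NTS-1 at 2 weeks. With the sample described as 16 h moved to 16 h it was 827 for HTS-3 at 16 h and 72 for the HTS-3 interaction, and with vehicle mice 1 to 5 alone 1 for NTS-1 at 2 weeks.

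Leaving out 1 mouse gave 77 to 118, 16 to 35 and 2 to 10 genes for NTS-1 at 8, 16 and 72 h, 3 to 201, 1 to 10 and 15 to 52 for TS-2, and 73 to 548 and 928 to 1691 for HTS-3 at 8 and 16 h. For TS-2 against NTS-1 it gave 77 to 231, 27 to 52 and 22 to 49 at 8, 16 and 72 h and 1918 to 3916 at 2 weeks, for HTS-3 against TS-2 30 to 409 and 799 to 1467 at 8 and 16 h, for the HTS-3 and TS-2 interactions 141 to 475 and 5 to 26, and at 2 weeks 165 to 1325 for NTS-1 and 4440 to 5680 for TS-2.

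Without vehicle 16 h mouse 1 the median of the endoplasmic reticulum folding list changed direction, to -0.14 for NTS-1 and -0.15 for TS-2, and the neutrophil median went to 0 for NTS-1 and for HTS-3. Without vehicle 16 h mouse 2 the medians were at their other extreme, 0.31 and 0.34 for the folding list and -2.09 and -2.13 for the neutrophil list. Of the other list values without 1 mouse 802 kept their side of the threshold and 143 lost it, and of those for named genes that passed 4076 kept it and 626 lost it. Of the values for genes that had not passed, 26 gained it and 3497 did not. At least 1 mouse decided 156 of the named gene calls and 63 of the list calls. Of 111 list calls 14 held with an estimated correlation and 92 with the filter at 32. Of 462 gene calls, interactions included, quantile normalization kept 437 and lost 25, the mean of probe sets kept 423 and lost 39, and the compared groups alone kept 210 and lost 252. Of 431 genes given without a call, quantile normalization added 3. On the single-dose arrays, signal near the floor limits what can be called, since 3231 of 18194 genes lay at it on every array.

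The larger direction of the calls turned for NTS-1 at 16 h with array weights, for TS-2 at 8 and 16 h without TS-2 mouse 4 and 3, for HTS-3 at 8 h without any 1 of its mice and with array weights, and for HTS-3 at 16 h without mouse 3, with quantile normalization and with the Actb covariate. It also turned for HTS-3 against TS-2 at 8 h without HTS-3 mouse 1 or 2 and with array weights and at 16 h with the Actb covariate, for the TS-2 interaction without any 1 of the 8 h vehicle mice, and for NTS-1 at 2 weeks with quantile normalization (438 higher and 427 lower). With the sample described as 16 h moved to 16 h it turned for HTS-3 against vehicle and against TS-2 at 8 h. On the compared groups alone the 1 gene called for TS-2 at 16 h, and for TS-2 against NTS-1 at 72 h, was higher, as was the 1 for NTS-1 at 2 weeks with vehicle mice 1 to 5.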

Other observations

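All of the counts here come from the planned tests, and none was chosen after its result was seen.

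Over the 18 comparisons, at the preset correlation, the macrophage list passed in 13 and the interferon list in 12, and the acute phase and apoptosis lists in 8 each. The endothelium, cytokine and endoplasmic reticulum folding lists passed in 6 each, the cholesterol, fatty acid synthesis and G2 lists in 5 each, and the integrated stress response, neutrophil, cytochrome P450 and G1/S lists in 4 each. The p53 and stellate cell lists passed in 3 each, the NRF2, lymphocyte, PPAR-alpha, coagulation, lysosome and RNase H lists in 2 each, and the red blood cell, urea cycle and gluconeogenesis lists in 1 each. With an estimated correlation 14 of these 111 passes held, 4 of them for the interferon list, 3 each for the cytokine and G2 lists and 2 each for the macrophage and apoptosis lists. The cholangiocyte, bile acid and circadian clock lists passed in 0 (by camera in limma).

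The Actb 3'/5' log2 ratio ran from 1.15 to 1.98 over the single-dose arrays and from 1.36 to 1.90 over the 2-week arrays.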
